A study of Mus musculus with 4 samples.

How the data were processed

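ATAC-seq peak lists of lung endothelial cells sorted by flow cytometry were analysed for 2 Dnmt3a KO and 2 WT mouse libraries, with genotype and replicate number taken from the labels. Per the labels' protocols, nuclei were isolated with detergent and digitonin, tagmented and amplified by PCR. The submitters' processing notes name cutadapt, Bowtie2, Picard and the mm10 build, without versions or roles. The peak caller, its threshold, the read filters and any shift of reads for the transposase were not given in the sources used here, nor was read depth. Each deposited list holds chromosome, start, end, width and strand for its own library, with no score, fold, p-value or read count. The only measurement is peak width in base pairs, a unit that the authors did not normalise, per the file headers. The narrowest peak was 201 bp in every list. A list with deeper sequencing or a looser threshold would hold more narrow peaks, so absence from a list does not show closed chromatin.

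Peaks on chromosomes 1 to 19, X and Y were kept. Peaks on other sequences, 92 and 134 in the KO lists and 134 and 124 in the WT lists, were left out. The 4 lists were joined into merged regions wherever peaks overlapped by at least 1 bp, and each region was described by the lists that called it. Regions called in 1 KO and 1 WT list served as the background, since they have the same number of calls. The Jaccard index was the shared over the total base pairs of 2 lists.

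The plan, fixed before the data were examined, used transcription start sites, exons and introns. The gene table used here (GRCm38.p6, the mm10 assembly) gives gene spans without strand or exons. Each region was therefore assigned from its centre to the nearest of 21887 protein-coding gene spans within 50 kb, and windows of 1000 bp around either gene end replaced the start site. All 408 list genes matched a symbol. CpG content, repeats and motifs need genome sequence and were not analysed here. Stricter calls and equal list lengths by peak score, fixed in the plan, were not run, and versions by width were added after seeing the data.

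Shares and list membership were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family (9 location tests, 24 lists, 21 chromosomes), at an adjusted p under 0.05. Intervals are 95% and cover counting error only (Wilson for shares). Library values were compared by a two-sided exact permutation test, which cannot go below p = 0.333 with 2 against 2. Gathering at genes, chosen after seeing the data, was compared with 10000 random draws from the 8357 assigned regions called in exactly 2 lists, or 2000 draws for alternatives. Widths of regions called in all 4 lists were compared with limma on quantile-normalised log2 width, also chosen after seeing the data.

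The named genes were Dnmt3a; per pattern, the first 15 genes by the lower of the 2 width percentiles; up to 3 members of each list; and the 5 genes with most regions of one pattern and none of the other. The rule foresaw width where no score is given. Some items that the rule or the tests gave are not reported here.

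The procedures were tested on simulated data. Of 1200 KO-pattern and 3000 WT-pattern regions planted among 40000, 90.25% and 90.17% were recovered. The call rates given to the planted regions largely set these shares, so they tested the merging and not the sensitivity for real regions. The simulated regions were drawn from regions called in all 4 lists, which are wider than the genotype-patterned ones. A planted list, at an odds ratio of 17.8, was called with 0 others among 24, and gathering planted at 60 genes gave 110 genes against 74.5 at random. Weaker list differences were not simulated, so they could have been missed. For widths over 75395 regions, 11 of 100 planted log2 shifts of 1 and 72 of 100 shifts of 2 were recovered, with 4 false calls. Alternatives covered the overlap rule, a 500 bp gap for absence, list length, gene distance, background, and leaving out each library. Not every result was run under each of them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used.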

Results

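Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in endothelial cells sorted by flow cytometry from mouse lung. There were 4 libraries, 2 from Dnmt3a knockout (KO) mice and 2 from wild-type (WT) mice. Dnmt3a encodes a de novo DNA methyltransferase, and the comparison asked how its loss altered the regions open in lung endothelium. Each library came as a list of peak positions on mm10 with no score or read count, so read depth was unknown and a difference was a difference in which peaks were listed or in how wide they were. On chromosomes 1 to 19, X and Y the lists held 85091 peaks in KO replicate 1, 100879 in KO replicate 2, 101442 in WT replicate 1 and 97627 in WT replicate 2. The labels did not say whether the 2 libraries of a genotype came from different mice, so p-values from library values measured only the spread between these libraries. Tests on numbers of regions measured counting error and not the spread between libraries.

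At Dnmt3a itself (gene identifier 13435, chromosome 12, 3801559 to 3914443), 23 merged regions lay in the gene or within 10 kb of it, and 16 of them were called in all 4 lists. Peaks in this interval numbered 17 and 23 in the KO libraries and 22 and 20 in the WT libraries. One region inside the gene, at 3825600 to 3826164, was called in both KO lists (387 and 565 bp wide) and in neither WT list, and 0 regions had the opposite pattern. Peak positions did not show the deleted sequence, so this locus did not check the genotype labels.

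**Figure D1:**
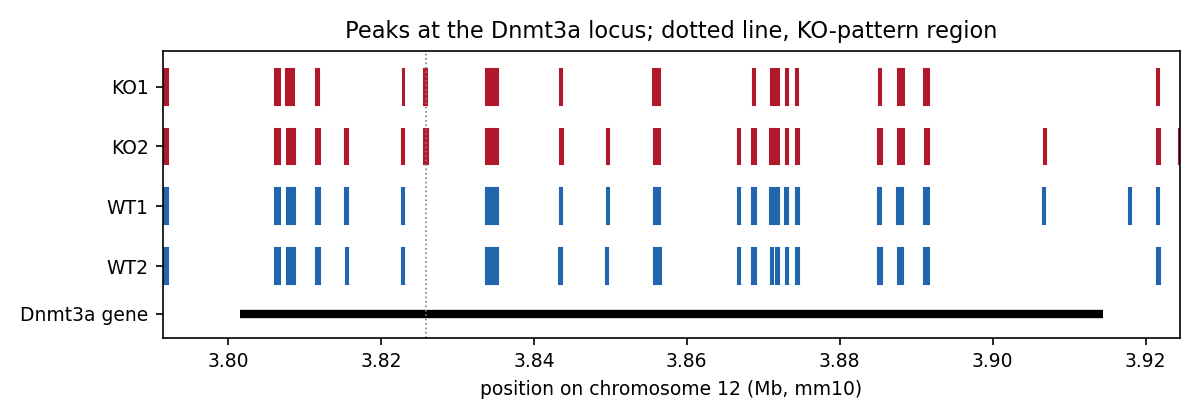
Peaks of the 4 libraries along chromosome 12 (x axis, Mb) at Dnmt3a, 1 row per library, KO in red and WT in blue, with the gene span as a black bar. Of the 23 regions, 16 are shared by all 4 lists, and the dotted line marks the KO-pattern region at 3825600 to 3826164.

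Most open regions were shared. The lists merged into 113056 regions, of which 75395 (66.7%) were called in all 4. Regions called in both KO lists and neither WT list (KO pattern) numbered 1267, and regions called in both WT lists and neither KO list (WT pattern) numbered 3434. Regions called in 1 KO and 1 WT list, which follow no genotype, numbered 593 to 2412 for each of the 4 possible pairs and 5331 in all. Taking the geometric mean of the 2 complementary counts, the genotype split gave 2086 regions against 1057 and 1196 for the other 2 ways of pairing the libraries. That is 1.74 times the larger of these, and 1.13 times with only peaks at or over the median width of their list. With 3 splits no p under 0.333 was possible. With each list limited to its widest peaks at the length of the shortest list, which also removes narrow peaks, the WT excess was gone: the KO pattern held 1952 regions and the WT pattern 1946. The shortest list, KO replicate 1, lost no peaks by this limit, while the WT lists lost their narrowest. A gain of KO-pattern and a loss of WT-pattern regions could therefore follow from the limit itself. Leaving out KO replicate 1, KO replicate 2, WT replicate 1 or WT replicate 2, which asks for 1 list fewer, gave 6571, 3471, 2325 and 2094 KO-pattern regions and 5631, 12028, 6394 and 8464 WT-pattern regions.

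**Figure D2:**
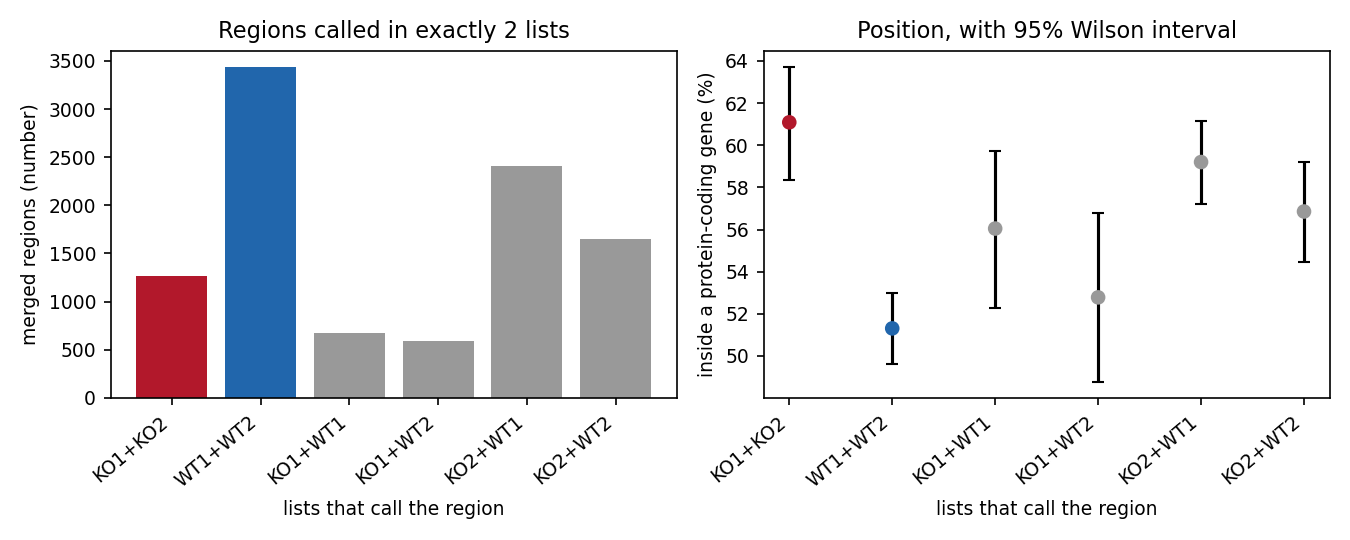
Left, the number of merged regions called in exactly 2 lists (y axis) for each pair of lists (x axis), with the KO pattern in red, the WT pattern in blue and mixed pairs in grey (KO1 is KO replicate 1, and so on). Right, the percentage of those regions inside a protein-coding gene with its 95% Wilson interval; the WT pattern is lowest at 51.3% and the KO pattern highest at 61.1%.

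Genotype-patterned regions were narrow. Their median width percentile within a list was 13.8 and 21.6 in the KO libraries for the KO pattern and 14.1 and 10.9 in the WT libraries for the WT pattern. Mixed regions had 9.42 to 12.3, with 12.3 in KO replicate 2 against 21.6 for its KO-pattern regions, and regions of all 4 lists had 55.1 to 61.9. Only 45 KO-pattern and 29 WT-pattern regions had both peaks at or over the median width of their list.

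KO-pattern regions were ranked by the lower of the width percentiles of their 2 peaks. The first lay inside Palld, which encodes the actin-associated protein palladin, at chromosome 8, 61549519 to 61550672, with peaks of 965 and 795 bp. It was followed by regions inside Lrrk2, a kinase gene mutated in Parkinson disease (1060 and 756 bp), Fignl2 (838 and 973 bp) and Stat5b, a cytokine-activated transcription factor (783 and 839 bp). The next genes in order were Alg14, Pdxdc1, Myl10, Pde9a, Lhx6, Ppp1r14a, Skida1, Ubtf, Tnfaip8l2, Ltbp1 and Rgcc. A WT peak lay within 500 bp of the ranked regions of Pde9a, Lhx6 and Ppp1r14a. The ranked regions of Myl10, Skida1 and Rgcc lay 6621, 2837 and 7499 bp from the gene. Of these 15 genes, Palld and Lhx6 also held 1 WT-pattern region each and Ltbp1 held 3, against 4, 2 and 2 KO-pattern regions. Among genes with at least 2 KO-pattern regions and 0 WT-pattern regions, of which there were 70, Meis2, a homeobox transcription factor, had 5, Klhl5 had 4, and Btn2a2 and Fignl2 were among those with 3.

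By the same ranking, the first WT-pattern region lay inside Ugt8a, which encodes a ceramide galactosyltransferase, at chromosome 3, 125937842 to 125938686, with peaks of 778 and 803 bp. The next lay 6082 bp from Hlx, a homeobox gene (720 and 980 bp). Atxn1, Tmem132e, Fgf21, Ppm1h, Alox12, Pcx, Snx27, Cap1, Emx1, Sall1, Gtf2ird1, Skap1 and Pax2 followed. A KO peak lay within 500 bp of the ranked regions of Pcx and Gtf2ird1. The ranked regions of Fgf21, Alox12 and Sall1 lay 7720, 20885 and 3111 bp from the gene. Hlx, Atxn1 and Gtf2ird1 also had 1 KO-pattern region each. Of 315 genes with at least 2 WT-pattern regions and 0 KO-pattern regions, St6galnac3, a sialyltransferase gene, had 7, Skap1, Fars2 and Ptprm had 6 each, and Aff3 had 5. In a test of each gene against its number of 2-list regions, 0 of 5107 genes passed the hypergeometric test after Benjamini-Hochberg adjustment, with 75 for KO and 40 for WT at an unadjusted p under 0.05. Few genes had enough such regions to pass on their own: 97 for KO and 7 for WT, had all their regions been of that pattern.

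KO-pattern regions lay together at genes more often than random draws. There were 124 genes with at least 2 of them, against a mean of 83.9 (95% range 70 to 99) in 10000 random draws of as many regions from those called in exactly 2 lists (permutation p = 0.0001, the smallest these draws can give), and 27 genes with at least 3, against 10.3 (5 to 16). WT-pattern regions gave 393 genes with at least 2, against 383 (358 to 407, permutation p = 0.229), and 110 with at least 3, against 88.3 (74 to 102, permutation p = 0.002). The mixed pairs lay within their random ranges, for example 245 genes for KO replicate 2 with WT replicate 1, against 257 (235 to 279). This test was chosen after the data were seen, and over its 12 comparisons the adjusted p was 0.0006 for both KO-pattern counts and 0.008 for 3 or more WT-pattern regions. Without KO replicate 1 it made no call: 1091 genes against 1076, permutation p = 0.213. Without KO replicate 2, WT replicate 1 or WT replicate 2, the counts were 462, 278 and 250, each above its random range.

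**Figure D3:**
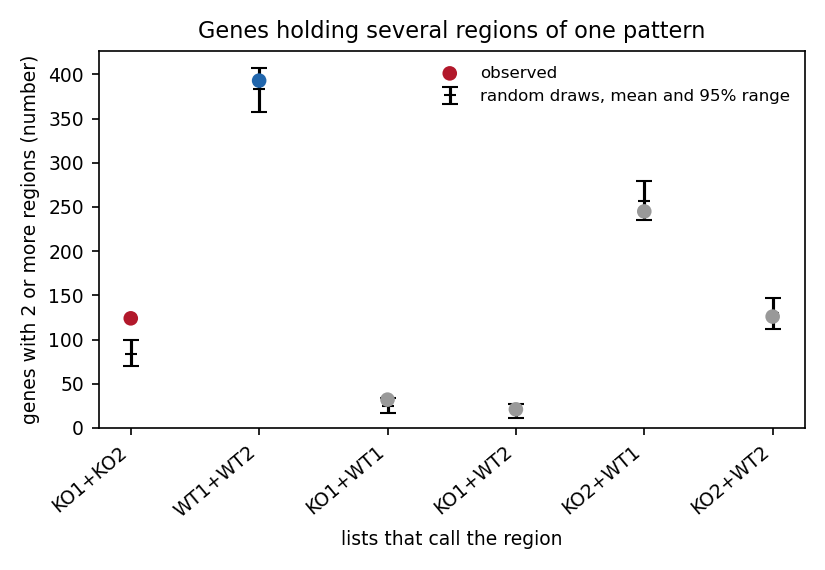
Number of genes with at least 2 regions of 1 pattern (y axis) for each pair of lists (x axis); coloured points are observed, and black bars give the mean and 95% range of 10000 random draws. The KO pattern, at 124 genes, lies above its range of 70 to 99, and the other 5 pairs lie within theirs.

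Of 24 gene lists fixed before the data were examined, 0 differed from mixed regions in either pattern after adjustment over the lists alone (Fisher's exact test with Benjamini-Hochberg adjustment), and 3 KO-pattern lists and 1 WT-pattern list had an unadjusted p under 0.05. Venous genes had 5 KO-pattern, 3 WT-pattern and 3 mixed regions (odds ratio 6.99 against mixed, Fisher's exact p = 0.00886, adjusted p = 0.213), with KO-pattern regions at Nrp2, a semaphorin and VEGF co-receptor, Nr2f2, a transcription factor of venous identity, and Vwf, which encodes von Willebrand factor. Nr2f2 also had a WT-pattern region, with wider peaks (424 and 520 bp) than its KO-pattern region (278 and 260 bp). The WT-pattern region lay 45972 bp from Nr2f2 and the KO-pattern region 4191 bp. The KO-pattern regions named at Nr2f2 and Vwf were lost with lists of equal length. Lymphatic endothelial genes had 3, 1 and 1, the 3 KO-pattern regions being those of Nrp2. Germline genes silenced by DNA methylation had 2, 1 and 0, both KO-pattern regions at Stk31. VEGF and angiogenesis genes had 6, 3 and 14, including KO-pattern regions inside Flt1 and 1669 bp from Kdr, the VEGF receptor genes. The 3 KO-pattern regions of Nrp2 were counted in the venous, lymphatic and VEGF lists alike. Fisher's test took such regions of 1 gene as independent. Pan-endothelial genes had 6, 14 and 22, with WT-pattern regions nearest Cldn5, a tight junction gene (3 regions), and Cdh5, the VE-cadherin gene. The regions named for them lay outside the genes, 26611 bp from Cldn5 and 22854 bp from Cdh5. Endothelial transcription factors had 12, 14 and 34, general capillary genes 2, 6 and 9, aerocyte genes 0, 3 and 1, and arterial genes 1, 3 and 2. Efnb2, the ephrin B2 gene, was nearest to 2 of the arterial WT-pattern regions, and the one named for it lay 3081 bp from the gene.

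BMP and TGF-beta pathway genes had 3 KO-pattern, 7 WT-pattern and 25 mixed regions, immediate early and stress genes 1, 2 and 4, inflammation and leukocyte adhesion genes 3, 2 and 6, and interferon and antigen presentation genes 0 of each. DNA methylation machinery genes had 2, 1 and 3. Developmental transcription factors of Polycomb target regions had 1, 9 and 7, among them WT-pattern regions at Pax2, Pax3 and En2. Hox genes had 2, 3 and 8 and imprinted genes 2, 2 and 6. Markers of other cell types were counted in the same order: epithelial 1, 2 and 1, fibroblast 0, 2 and 13, mural 1, 0 and 1, lymphocyte 0, 5 and 1, myeloid 0, 1 and 2, platelet and erythroid 1, 1 and 0, and pan-leukocyte 1, 3 and 3. Lymphocyte markers were the WT-pattern list with an unadjusted p under 0.05 (odds ratio 8.37 against mixed, Fisher's exact p = 0.0303, adjusted p = 0.604). Their WT-pattern regions lay at or near Cd2, Pax5 and Cd3e.

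All 23 pan-endothelial genes had a peak within 1000 bp of a gene end in each library. Of 92 markers of other cell types, 43 and 49 did so in the KO libraries and 48 and 44 in the WT libraries (difference in means 0, exact permutation p = 1). Single lists went both ways: pan-leukocyte genes numbered 4 and 5 in KO against 3 and 3 in WT, and epithelial markers 8 and 9 against 10 and 9. Lymphocyte markers numbered 6 and 7 in KO against 7 and 7 in WT. With a window of 2500 bp around the gene ends, pan-leukocyte genes numbered 7 in every library. In that window epithelial markers numbered 10 and 10 in KO against 10 and 11 in WT, and lymphocyte markers 7 and 9 against 9 and 9. Peaks at or near single-copy Y genes were found for 4 of 5 genes in KO replicate 1, 0 in KO replicate 2, 3 in WT replicate 1 and 4 in WT replicate 2. KO replicate 2 alone had 2 peaks in the 2500 bp at the high-coordinate end of Xist, the RNA gene that silences an X chromosome in females, at 103481432 to 103482164 and 103483099 to 103483433 on chromosome X. Peaks on chromosome Y numbered 41 and 39 in KO and 40 and 44 in WT. The share of peaks on chromosome X was 2.14% and 2.13% in KO and 2.10% and 2.08% in WT. Neither set KO replicate 2 apart. The chromosome Y total could not tell sex, since KO replicate 2 listed 39 such peaks with 0 at the 5 Y genes. By the Y-gene and Xist peaks, KO replicate 2 looked female and the other libraries male. The KO libraries thus appeared to differ in sex, which was not checked against a label. If they did, they came from different mice, while for the WT libraries this stayed unknown. The KO pattern required both KO libraries.

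WT-pattern regions lay inside protein-coding genes less often (51.3%) than mixed regions (57.4%; odds ratio 0.783, 95% interval 0.718 to 0.855, Fisher's exact test, adjusted p = 8.9e-08), and 20.7% lay over 50 kb from any such gene, against 14.7% (odds ratio 1.52, adjusted p = 3.6e-12). KO-pattern regions lay inside genes more often (61.1%; odds ratio 1.17, interval 1.03 to 1.33, adjusted p = 0.029). The mixed pairs themselves ranged from 52.8% (interval 48.8 to 56.8; KO replicate 1 with WT replicate 2), which overlaps the WT pattern, to 59.2% (57.2 to 61.1; KO replicate 2 with WT replicate 1), which overlaps the KO pattern and holds 2412 of the 5331 mixed regions. The share also followed 1 library: regions missing from KO replicate 2 alone were inside genes in 50.5% of cases and regions missing from KO replicate 1 alone in 57.5% (odds ratio 0.753, Fisher's exact p = 8.2e-09). Regions called only in KO replicate 2 were inside genes in 62.0% of cases, near the share of the KO pattern. Those called only in KO replicate 1, WT replicate 1 or WT replicate 2 were so in 56.5%, 55.4% and 54.5%. The share within 1000 bp of a gene end was 5.29% for the KO pattern, 5.18% for the WT pattern and 4.90% for mixed regions, with no difference past the threshold (adjusted p = 0.705 for each pattern against mixed regions), and 17.7% for regions of all 4 lists.

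Chromosome 8 held 106 KO-pattern regions, 8.37% of them against 5.20% of mixed regions (odds ratio 1.67, adjusted p = 6.6e-04 over 21 chromosomes), and chromosome 12, which holds Dnmt3a, held 30, 2.37% against 4.37% (odds ratio 0.531, adjusted p = 0.0078). In windows of 5 Mb along chromosome 12, the first, which holds Dnmt3a, had 2 KO-pattern and 6 mixed regions. Windows with 0 KO-pattern regions lay next to it (from 5 Mb, 6 mixed) and far from it (from 100 Mb, 23 mixed). The window from 105 Mb had 4 KO-pattern and 9 mixed regions. For the WT pattern 0 chromosomes passed the adjusted test, the smallest adjusted p being 0.113. Regions are not independent samples of animals.

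The lists were compared as whole sets. The Jaccard index by base pairs was 0.708 between the KO lists, the lowest of the 6 pairs, and 0.823 between the WT lists, the highest. KO replicate 2 reached 0.778 with each WT list, and KO replicate 1 reached 0.720 and 0.739. The mean was 0.766 within genotypes and 0.754 between them. By the share of merged regions called in both lists, the KO lists had 76.8%, and the lowest pair was KO replicate 1 with WT replicate 1, at 76.4%. KO lists held 92985 ± 11164 peaks and WT lists 99534.5 ± 2698 (SD, n = 2 each, exact permutation p = 0.667), and covered 47.2 ± 0.81 Mb and 50.8 ± 0.45 Mb (SD, n = 2 each, exact permutation p = 0.333, the smallest this design allows). Without KO replicate 1 the sign of the difference in peak number turned, to 1344.5 more in KO. At the 75395 regions of all 4 lists, limma on log2 peak width found 0 regions that differed after adjustment (smallest adjusted p = 0.437), with 3665 (4.86%) at an unadjusted p under 0.05. That unadjusted count was 8911 without KO replicate 1, 14014 without KO replicate 2, 1884 without WT replicate 1 and 2068 without WT replicate 2, with 0 after adjustment each time.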

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

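The versions by width, the gathering of regions at genes, the width comparison and the crossed pairing were chosen after seeing the data. Stricter calls by score, CpG content and motifs, fixed before the data were examined, were not run, since the lists hold no score and no sequence was used. Requiring a larger overlap or a 500 bp gap kept the KO count (1227 and 1023) and the WT count (3437 and 3139) within 1.5 times. With only peaks at or over the median width of each list they were 635 and 1702, with equal lengths 1952 and 1946, and with wide calls and lenient absence 45 and 29; the WT to KO ratio turned to 0.997 with equal lengths and 0.644 with wide calls. Of 109 named gene and pattern pairs, the named region kept its pattern in 106 with the larger overlap, 95 with the gap, 73 with equal lengths, 33 with only the wider peaks and 33 with wide calls and lenient absence. Leaving out each library, which asks for 1 list fewer, gave 2094 to 6571 KO-pattern and 5631 to 12028 WT-pattern regions. The genotype split over the larger other split fell from 1.74 to 1.13 with only those wider peaks; the cause was not tested. The odds ratio for a gene end, past no threshold against mixed regions, was 0.346 for KO and 0.334 for WT against all merged regions, where regions of all 4 lists dominate, and 0.985 for KO with equal lengths. The difference in peak number ranged from -14443.5 to 1344.5 without each library. Genes with at least 2 KO-pattern regions, 124 as reported, numbered 115 with the larger overlap, 217 with equal lengths, 93 with the gap and 78 by nearest gene end, each above its random range. Without each library they ranged from 250 to 1091, and the call was lost without KO replicate 1; the cause was not tested. List calls stayed at 0 and chromosome calls at 2 and 0 under every alternative run for them. Width calls were 0 in each setting, which shows little about stability, since 11 of 100 simulated log2 shifts of 1 were recovered; without a library, the lone library of its genotype was assumed to vary like the other genotype.

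The replicate numbers were not taken to pair the samples: there are 2 pairs, and no label ties a number to a litter or day. With the replicate block the pattern counts were 1267 and 3434, equal by construction, the difference in peak number was -6549.5 (exact sign-flip p = 1), same-numbered lists differed from other pairs by -0.0128 in Jaccard index, and 0 widths were called. Those other pairs include the pairs within a genotype. Among pairs of 1 KO and 1 WT list, the mean index was 0.749 for same-numbered and 0.758 for other pairs. Same-numbered deviations of log2 width correlated at -0.107 with median centring (-0.0854 with quantile normalisation), and the crossed pairing also called 0 widths.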

Other observations

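The tests on KO replicate 2, on list length and on the library behind the gene share were chosen after the results were seen, as was the comparison with mixed pairs.

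KO-pattern regions gathered at genes, with at least 2 such regions at 124 genes. Pairs of KO replicate 2 with a WT library did not gather (245 genes for WT replicate 1, within the random range). Pairs of KO replicate 1 did not either (32 genes with WT replicate 1, range 17 to 34, and 21 with WT replicate 2, range 11 to 27). These counts cannot exclude 1 KO library, or its sex, as the source, since the random draws also held regions called in that library. The call was lost without KO replicate 1 (1091 genes against 1076 at random), so dependence on KO replicate 1 also stays open. With regions of a gene within 5 kb counted once, 107 genes had at least 2, above the random range of 65 to 94, so splitting of broad peaks is not the whole source. A candidate explanation is that loss of Dnmt3a acts on whole gene neighbourhoods: peaks called in all 4 lists at these genes were wider in KO by a mean log2 difference of 0.02771 (random range -0.0105 to 0.0193), and at genes with at least 2 WT-pattern regions they were wider in WT by 0.0251 (-0.0105 to 0.00891). The 4 mixed pairs gave smaller differences in their own splits, 0.0140 to 0.0163, but 2 of them passed the same test, so genotype cannot be told apart from regional variation between libraries, and the difference in size was not tested.

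WT-pattern regions lay inside genes less often than mixed regions (51.3% against 57.4%). Absence from the list of KO replicate 2 may account for part of this, since regions missing from that list alone were inside genes in 50.49% of cases, against 57.5% of those missing from KO replicate 1 alone. Whether sex, genotype or the library sets this was not tested. WT-pattern regions also outnumbered KO-pattern regions, by 2.71 times. The shorter list of KO replicate 1 could be the source, since at equal lengths by width the ratio was 0.9969, but that limit also removes narrow WT peaks whatever their origin. The counts of regions called in 1 list predicted a ratio of 1.27, and those of regions called in 3 lists 20.7. A genotype effect would change these counts too, so the values do not decide between list length and genotype.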
